A study of Mus musculus with 6 samples.

How the data were processed

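Total RNA of spleen NK cells from 6-week-old wild-type C57BL/6 mice was extracted with Trizol, per the labels' protocols, and poly(A) RNA was taken from 5 µg. Libraries were made with a TruSeq RNA v2 kit, with inserts of about 300 bp, and sequenced as paired reads of 150 bp on a NovaSeq 6000, per the labels' protocols. This kit does not mark the strand, so reads of a gene and an overlapping antisense gene cannot be told apart. The submitters' processing notes name HISAT, StringTie, edgeR and the build GRCm38 (mm10), with no versions or settings. Per the file headers, the deposited table gives an FPKM value (fragments scaled to transcript length and library depth) and a count for each gene row and library. Of its 27763 gene identifiers, 27695 were found in GENCODE release M21 on GRCm38, all on the same chromosome, and 25921 had the same start and end.

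The deposited counts are whole numbers but not read counts. In rows with 1 listed transcript the low values pile up at 4 and 8, and 89.3 to 91.3% of values up to 30 equal FPKM times transcript length times a constant per library, rounded up. They were therefore treated as estimated counts derived by the authors from coverage, already whole, with 1 read pair worth about 3.76 of them. Of the same low values only 42.4 to 44.7% lay near a whole number of read pairs. The unit is thus approximate, as are the floors and intervals built on it. Estimated counts per library ranged from 79798234 to 89526647. The planned test, written before the data were examined, was limma on log2(FPKM + 1). Because the table also held counts, edgeR's quasi-likelihood test on the estimated counts became the main test, as the plan foresaw for that case, and limma on FPKM became an alternative. Since the counts overstate the number of independent fragments, counts divided by the worth of 1 read pair were run as well.

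Rows with at least 1 FPKM in at least 3 of the 6 libraries were tested, 11690 rows holding 99.26% of the estimated counts. The fit used TMM factors (0.973 to 1.03), robust dispersion and robust quasi-likelihood with edgeR 4.0.16 in R 4.3.3, 2-sided, with group as the only term and Benjamini-Hochberg adjustment over all tested rows. The threshold was an adjusted p of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation was 13.5%. FPKM means and SDs are of the deposited values. Where all cNK libraries were at 0, the fold was computed against a floor of 3 read pairs (11.3 estimated counts) over the group. Where cNK held 1 to 3 read pairs, the ratio of summed counts has an exact 95% binomial interval. Floors and intervals cover counting error only, since no molecular identifiers are named in the sources used here.

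Before the data were examined, 29 gene lists were fixed, with 701 entries, of which 674 matched a symbol, 1 shared a row with another member and 26 were not listed in the table. The lists cover NK lineage, mature and immature stage, transcription factors, cytotoxic effectors, cytokines, Ly49 and NKG2 receptors, trafficking, ILC1 and residency, cytokine receptors, checkpoints, cell cycle, interferon, immediate early and stress genes, glycolysis, oxidative phosphorylation, ribosomal proteins and class II presentation. The others hold markers of B cells, plasma cells, T cells, monocytes and macrophages, neutrophils, dendritic cells, basophils and mast cells, ILC2 and ILC3, erythroid cells, platelets, and stroma and endothelium. The 24 lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. Camera called 18 of them, of which 2 (mature NK stage, and ILC1 and tissue residency) held with an estimated correlation. Fry called 22 with a direction, among them transcription factors, interferon response and glycolysis, which camera did not call. The list calls given below rest on camera. Lists share members, so their calls are not independent. Members that also stand in another list numbered 16 of 22 for ILC1 and residency, 9 of 16 for mature stage and 10 of 18 for immature stage. The genes named were fixed by rule: 9 anchors; the 8 largest higher and 8 largest lower changes past the threshold without overlap of the groups, leaving out gene models, clone names, immunoglobulin and T cell receptor segments; and up to 3 members of each list with the largest change past the threshold, or the most abundant tested member where none passed. The rule also let other list members be named without statistics; those given with values, and those picked from among them, were chosen after their values were seen. Some genes that the rule takes are not reported here. The genes shown in the plots by library were also chosen then. In the named set 87 of 88 tested rows passed, and all 87 had no overlap between the groups, so every fold described as past the test was higher or lower in 3 of 3 libraries. The same held for all 354 distinct list members past the threshold.

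The test was checked on simulated counts for all 11690 rows of this comparison with 200 rows changed. It recovered 7 of the 50 rows given the smallest change, 62% at 1.5-fold, 88% at 2-fold and 98% at 4-fold. The same run made 20 false calls, a larger share of its calls than the adjusted p threshold of 0.05 allows. This was a single run with 200 rows changed, whereas 7215 rows passed in the real comparison, so its share of false calls cannot be carried over. The calls in the real comparison may still hold more false ones than that threshold states. Where nothing was changed, the test made 1 call. Camera called a simulated list of 30 rows raised 1.5-fold and made no call for an unchanged list of the same size. The simulated rows varied independently of each other, so this check cannot show how camera performs where genes are correlated. Replicates of a group differed beyond counting noise, with a median chi-square per gene of 1.11 to 1.80 where counting alone gives 0.455, so no library was treated as a copy of another. Pearson correlations of log2 depth-scaled counts between libraries were 0.987 to 0.989 within groups and 0.914 to 0.934 between groups. These are correlations across genes, which are not independent replicates.

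The alternatives were pseudocounts of 0.1 and 0.01 FPKM, no filter, a mean of at least 5 FPKM, rescaling each library to a common sum, upper quartile and quantile scaling, limma without a trend and with array weights, a replicate block, rows summed by symbol, and each library left out. Added after seeing the data were DESeq2 1.42.0, edgeR with median-ratio scaling, with upper quartile scaling, without scaling factors and with its default expression filter, counts per read pair, and the KEGG pathways of the deposited annotation tested with camera. Figures were drawn with matplotlib 3.10.9.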

Results

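Gene expression was measured by poly(A) RNA sequencing in natural killer (NK) cells from the spleen of 6-week-old wild-type C57BL/6 mice. The libraries fall into 2 groups, cNK and DN NK, with 3 libraries each. The labels spell out neither short name nor the surface markers behind it, so a gene that served to separate the groups is not known here to be an outcome. The series title places the study around an immature NK subset residing in the spleen and a role of T-bet in its maturation. The deposited table holds 27763 gene rows with an estimated count and an FPKM value per library. The estimated counts summed to 89526647, 86613931 and 84270567 in cNK replicates 1, 2 and 3. They summed to 81437724, 81007387 and 79798234 in DN NK replicates 1, 2 and 3. A read pair was worth about 3.76 estimated counts, so the number of sequenced fragments behind each total is smaller by about that factor. Rows above 0 numbered 21468 ± 83.7 in cNK and 22729 ± 300.2 in DN NK (SD, n = 3 each). The labels do not say whether the 3 libraries of a group came from separate mice, so p-values measure only the spread between these libraries. All values below are mean FPKM ± SD over 3 libraries per group, and fold changes and adjusted p come from edgeR with DN NK over cNK.

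The comparison of DN NK with cNK asks how the transcriptomes of these NK cell groups differ. In DN NK, 15 of 16 tested genes of the mature NK stage, 15 of 20 cytotoxic effector genes and 18 of 22 Ly49 and NKG2 receptor genes were lower. By camera the 3 lists moved down, but with an estimated correlation only the mature stage list kept its call (adjusted p = 0.0162, against adjusted p = 0.0507 for cytotoxic effectors and adjusted p = 0.133 for the receptors). Higher were 19 of 20 tested genes known from type 1 innate lymphoid cells (ILC1) and tissue-resident lymphocytes, such as Il7r, which encodes the interleukin-7 receptor chain, at 65.5 ± 2.81 against 2.71 ± 0.110 FPKM. All tested markers of B cells (12), plasma cells (5) and ILC2 or ILC3 (7) and 13 of 15 of T cells were higher in the same DN NK libraries. In cNK only 4 of 17 B cell, 1 of 8 plasma cell, 2 of 16 ILC2 or ILC3 and 9 of 22 T cell markers reach 1 FPKM. The filter admits the rest mainly where DN NK is high, so these counts and their camera p-values partly follow from it. Without a filter 17, 7, 12 and 17 were higher, in that order, and only 2 T cell markers were lower. With an estimated correlation none of these 4 lists was called, at adjusted p = 0.0507 for T cells and adjusted p of 0.125 to 0.168 for the others. Of 11690 rows tested, 7215 passed an adjusted p of 0.05, with 3602 higher and 3613 lower in DN NK. A change of at least 2-fold was reached by 1472 of them, 924 higher and 548 lower. The 2-fold count depended on the filter and the scale, and was 592 with a mean of at least 5 FPKM, 2824 without a filter and 908 with limma on log2(FPKM + 1). In 7158 of the 7215 rows the libraries of the 2 groups did not overlap. Over all tested rows this held for 8141, or 69.6%, where chance gives 10%. The first principal component held 81% of the variance and separated the groups.

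The genes chosen as anchors before the data were examined gave a lower level of most NK-defining transcripts in DN NK, though they stayed well expressed. Ncr1, which encodes the activating receptor NKp46, stood at 206 ± 23.2 FPKM against 396 ± 45.5, a log2 fold change of -0.88 (SE 0.10, adjusted p = 0.000175). Klrb1c, the gene of the NK1.1 antigen, was at 139 ± 10.6 against 301 ± 15.6 FPKM (log2 fold change -1.05). The T-box factor genes Tbx21 and Eomes fell by 0.74 and 1.10 on the log2 scale, Tbx21 from 124 ± 7.23 to 71.1 ± 7.67 FPKM and Eomes from 154 ± 5.46 to 69.1 ± 1.85 FPKM. Itga2, which encodes the integrin chain CD49b, was 3.38-fold lower at 14.5 ± 0.770 against 51.0 ± 3.50 FPKM. Itgam, the gene of the maturation marker CD11b, was 4.52-fold lower at 16.2 ± 3.24 against 76.7 ± 7.04 FPKM. Cd27 was 1.33-fold lower, at 26.0 ± 0.564 against 35.9 ± 1.51 FPKM. Itga1, the gene of CD49a, lay below the filter in both groups at 0.255 ± 0.0125 and 0.159 ± 0.0148 FPKM, and in the fit without a filter its log2 fold change was 0.68 (SE 0.14, adjusted p = 0.00222). Cd3e, a chain of the T cell receptor complex, also lay below the filter at 0.846 ± 0.122 against 0.0218 ± 0.0214 FPKM, with a log2 fold change of 5.14 (SE 0.55, adjusted p = 0.000166) without a filter.

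In the deposited coordinates, which are whole-gene spans on GRCm38 per the submitters' processing notes, Ncr1 (ENSMUSG00000062524) lies on chromosome 7 from 4337724 to 4345164 on the plus strand. Tbx21 lies on chromosome 11 from 97098071 to 97115331 on the minus strand, and Eomes on chromosome 9 from 118478212 to 118486132 on the plus strand. Itga1 and Itga2 are neighbours on the minus strand of chromosome 13, from 114953096 to 115101964 and from 114833081 to 114932100. Klrb1c spans 128778485 to 128789215 on the minus strand of chromosome 6, and Itgam 128062640 to 128118491 on the plus strand of chromosome 7. Il7r spans 9506161 to 9529876 on the minus strand of chromosome 15.

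**Figure D1:**
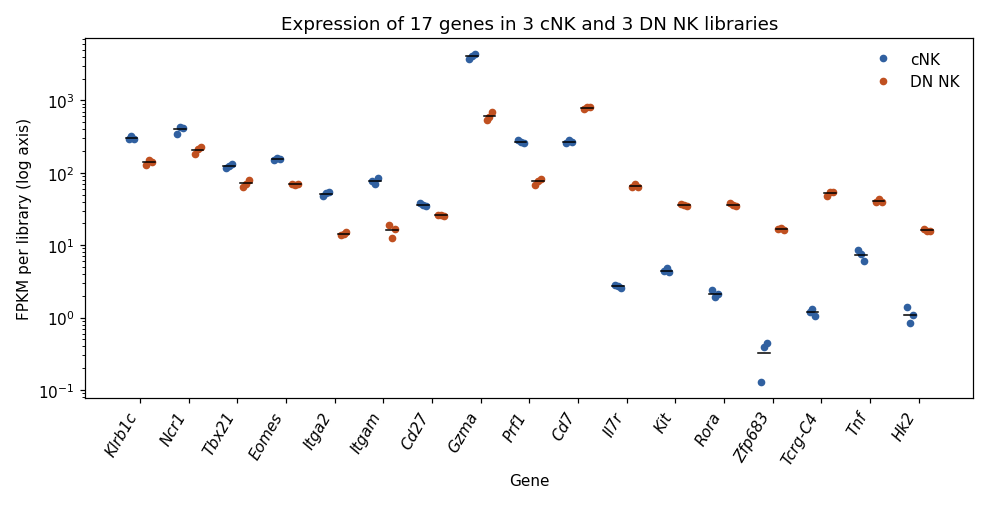
FPKM per library on a log axis for 17 genes, with 3 cNK points in blue, 3 DN NK points in orange and a black line at each group mean. The 10 genes on the left hold NK-defining and cytotoxic genes plus Cd7, and the 7 on the right are those far lower in cNK, from Il7r at 2.71 against 65.5 FPKM to Hk2 at 1.10 against 16.1 FPKM.

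NK transcripts differed between the groups to varying degrees. Of 17 tested NK lineage receptors and signalling genes, 12 fell, 2 rose and 3 did not pass, with 1 higher without cNK replicate 1, DN NK replicate 2 or DN NK replicate 3, and in 10 other alternatives. Sh2d1a, which encodes the adaptor SAP, fell by 1.63 on the log2 scale, while Cd7 rose 3.06-fold to 793 ± 34.6 FPKM. Il2rb, Zap70 and Hcst lay at log2 fold changes of 0.08, 0.05 and -0.07 and did not pass. Of 16 genes of the mature NK stage, 15 fell and none rose, with Cma1 3.88-fold lower (adjusted p = 2.66e-07) and S1pr5, a receptor for exit from tissues, 3.84-fold lower. Cx3cr1 lay at -0.54 and did not pass. The 24 matched Ly49 and NKG2 family receptors gave 18 lower, 3 higher and 1 not past among 22 tested. Klre1, Klra4 and Klra3 fell by 1.79, 1.75 and 1.74, and the near-identical Klra copies may share reads, so single Klra values are uncertain. Klrb1b, Klri1 and Klrc1 were the 3 higher members. Adjusted over the list alone, the counts for these 3 lists were the same. By camera the lists moved down with adjusted p of 4.45e-05 (NK lineage), 1.45e-12 (mature stage) and 1.60e-09 (Ly49 and NKG2). The mature stage list kept its call with adjusted p = 0.0162 with an estimated correlation, whereas the others gave adjusted p = 0.201 and adjusted p = 0.133 with an estimated correlation.

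Cytotoxic effector genes fell in DN NK for 15 of 20 tested members, 4 rose and 1 did not pass. Gzma, the granzyme A gene, fell 6.45-fold from 4037 ± 294.8 to 601 ± 75.1 FPKM. Gzmk fell 36.2-fold, from 7.11 ± 0.661 to 0.181 ± 0.0474 FPKM. Prf1, the perforin gene, fell by 1.76 on the log2 scale, and Fasl by 1.87. Tnfsf10, which encodes the death ligand TRAIL, rose 4.21-fold. Adjusted over the list alone, 15 fell and 4 rose. The list moved down by camera at adjusted p = 6.62e-06, and adjusted p = 0.0507 with an estimated correlation.

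Among 15 tested cytokines and chemokines, 9 rose, 4 fell and 2 did not pass. Il22 was at 2.36 ± 0.642 FPKM in DN NK and at 0 in all 3 cNK libraries, which makes it at least 72.6-fold higher against a floor of 3 read pairs over the cNK group. Lta rose 19.3-fold and Tnf 5.75-fold, to 41.0 ± 2.52 FPKM. Csf2 was also higher, while Ifng was at a log2 fold change of -0.02 and did not pass. Ccl3, Ccl4 and Ccl5 fell. The counts were the same adjusted over the list alone. The list was up by camera at adjusted p = 0.0259, which 9 of 23 alternatives ended (range 0.00477 to 0.384), and at adjusted p = 0.365 with an estimated correlation. Markers of ILC2 and ILC3, a list that also holds Il22, rose in the same libraries.

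Genes of the immature NK stage went both ways. Of 18 tested, 11 rose, 6 fell and 1 did not pass. Il7r rose 25.2-fold (adjusted p = 9.70e-09) and Kit, a growth factor receptor gene, 8.45-fold to 35.9 ± 1.26 FPKM. Cd81 rose 9.62-fold, while Cd27, Il18r1 and Cd2 fell. The counts adjusted over the list alone were the same. Its upward shift had a camera adjusted p of 0.00844, lost in 4 of 23 alternatives (range 0.000805 to 0.220), and adjusted p = 0.125 with an estimated correlation. Of 36 transcription factors of NK cells and innate lymphoid cells (ILCs), 15 rose, 13 fell and 8 did not pass, also adjusted over the list alone, and the list had no direction by camera (adjusted p = 0.384). Zfp683, the gene of the residency factor Hobit, rose 54.3-fold, and Rora 17.7-fold to 36.2 ± 1.63 FPKM. Id3, Ahr and Ikzf2 also rose, while Zeb2, Prdm1, Klf2, Myb and Irf8 fell. Rora also stands in the list of ILC2 and ILC3 markers, whose tested members were all higher in these libraries.

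Genes of ILC1 and tissue residency rose together. Of 20 tested members 19 rose and none fell, also adjusted over the list alone, and Rgs2 was at 0.04 and did not pass. Without a filter 20 of 22 rose and 1 fell, and 14 of the 22 reach 1 FPKM in cNK. Of the 22, 16 also stand in another list, so this rise is not separate from those of the other lists. Gpr55 rose 102-fold (log2 fold change 6.67, SE 0.10, adjusted p = 1.21e-08) and Tcrg-C4, a T cell receptor gamma constant gene, 45.3-fold to 51.7 ± 3.30 FPKM. Cd200r1, Inpp4b, Tmem176a and Tmem176b rose as well. The list moved up at a camera adjusted p of 1.92e-17, and adjusted p = 0.0162 with an estimated correlation. Among 26 trafficking and retention genes, 16 fell, 7 rose and 3 did not pass, and these counts were the same adjusted over the list alone; 11 rose without a filter and with edgeR's default filter. Cxcr6, a chemokine receptor of tissue-resident lymphocytes, rose 17.6-fold and Gpr183 8.31-fold. Itgb3 rose 6.80-fold. S1pr1, S1pr5 and the chemokine receptor gene Ccr2 fell, with Ccr2 4.73-fold lower. The list moved down by camera at adjusted p = 0.00258, which 1 alternative (quantile normalization, adjusted p = 0.0641) ended, in a range of 0.00196 to 0.0641, and gave adjusted p = 0.125 with an estimated correlation. Markers of T cells, B cells and ILC2 or ILC3 rose alongside in DN NK.

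Cytokine receptors rose for 14 of 22 members and fell for 4, with 4 not past; adjusted over the list alone 15 rose and 4 fell. Il2ra, which encodes the interleukin-2 receptor alpha chain, rose 28.3-fold and Il1r1 43.4-fold, while Il18r1, Il18rap and Il10rb fell. The folds of Il2ra and Il1r1 rest on low cNK values of 0.215 and 0.028 FPKM. Without a filter 13 of 29 list members rose and 5 fell. This list had a camera adjusted p of 0.000533, and adjusted p = 0.0574 with an estimated correlation. Checkpoint and costimulation receptors rose for 13 of 19 members, 1 fell (Lair1) and 5 did not pass, also adjusted over the list alone; 2 fell without cNK replicate 1 or 2 and in 11 other alternatives. Btla rose 50.9-fold and Ctla4 18.4-fold, and Cd200r1 13.1-fold, from low cNK values of 0.068, 0.449 and 0.491 FPKM. Lag3, Cd160 and Cd28 were higher as well. Without a filter 15 of 27 list members rose and 2 fell. For the list, the camera adjusted p was 2.82e-05, and adjusted p = 0.0507 with an estimated correlation. Btla and Cd28 are also used by B or T cells, whose markers rose in DN NK.

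Cell cycle genes were lower in DN NK for 27 of 36 members, 2 were higher and 7 did not pass; adjusted over the list alone, 27 fell and 5 rose. With DESeq2 and with median-ratio scaling in edgeR 4 were higher, and with a mean of at least 5 FPKM 11 were lower. Ccna2, Ccnb2 and E2f2 fell 3.94-fold, 3.90-fold and 3.83-fold, and Mki67 and Top2a also fell. The downward shift had a camera adjusted p of 3.89e-08, and adjusted p = 0.0749 with an estimated correlation. Oxidative phosphorylation genes fell for 32 of 49 members and rose for 1 (3 without cNK replicate 1), also adjusted over the list alone, with small sizes (median log2 fold change -0.24). Ndufb3, Ndufa8 and Ndufv2 of respiratory complex I fell by 0.97, 0.83 and 0.83. As a list they moved down at a camera adjusted p of 0.000106, and adjusted p = 0.0938 with an estimated correlation. Of 17 glycolysis genes, 7 rose, 5 fell (3 without cNK replicate 3 or DN NK replicate 1) and 5 did not pass, also adjusted over the list alone. Hk2, the hexokinase 2 gene, rose 15.2-fold and the glucose transporter gene Slc2a1 2.11-fold, while Eno1 fell 1.60-fold. The list had no direction by camera (adjusted p = 0.377). Cytosolic ribosomal protein genes hardly moved, with 11 of 75 higher and 8 lower (5 and 3 adjusted over the list alone), sizes up to 0.30 and camera adjusted p = 0.901. Without cNK replicates 1, 2 and 3 in turn, 14, 6 and 5 were higher and 4, 5 and 7 lower. Without DN NK replicates 1, 2 and 3 in turn, 5, 5 and 11 were higher and 13, 3 and 4 lower. The counts turned with scaling within each method. Limma gave 24 higher and 3 lower after quantile normalization against 5 and 15 with upper quartile scaling, and edgeR 12 and 6 with median-ratio scaling against 5 and 25 with upper quartile scaling. Without a filter 5 were higher and 18 lower. Rplp1 and Rps20 rose 1.21-fold and Rpl39 fell 1.23-fold with the scaling used here.

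Interferon response genes split, with 11 of 27 higher, 7 lower and 9 not past, also adjusted over the list alone. Ifi27l2a rose 3.51-fold and Ifit1 2.36-fold, whereas Ifit2 fell 3.05-fold, and camera gave adjusted p = 0.191. Immediate early and stress genes gave 18 of 35 higher, 10 lower and 7 not past, also adjusted over the list alone. Ier3 rose 4.11-fold, Gadd45b 3.32-fold and Hspa1b 3.21-fold, while Fos, Dusp1 and Nr4a1 fell. Upward movement of the list had a camera adjusted p of 0.0253, which 4 of 23 alternatives ended (range 0.00685 to 0.337), among them the fit without cNK replicate 3 (adjusted p = 0.0780). It gave adjusted p = 0.522 with an estimated correlation.

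The largest single changes included genes outside these programmes. Cryaa and Ifitm1 were at 1.53 ± 0.239 and 1.15 ± 0.0463 FPKM in DN NK and at 0 in all 3 cNK libraries, at least 50.2-fold and 35.1-fold higher. Cntn1 and Kcnk1 had 3 and 1 read pairs in cNK and ratios of 330.0 (95% counting interval 99.7 to 1420) and 342 (64.8 to 14400). Among lower genes, Klhl30 fell 17.4-fold from 12.5 ± 1.47 to 0.688 ± 0.0741 FPKM. Clip3, C1ql3 and Ret fell 27.7-fold, 23.4-fold and 16.9-fold from 2.72, 1.97 and 1.58 FPKM. Rows of the small nucleolar RNA genes Rnu3b1, Rnu3b2 and Rnu3b4 were among the largest lower changes, and other rows of Rnu3b2 and Rnu3b4 among the largest higher ones. Each of the 3 symbols occurs as a higher and a lower row at the same start, with ends that differ by 1 base, so these overlapping rows are uncertain and are not read as changes of a gene.

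**Figure D2:**
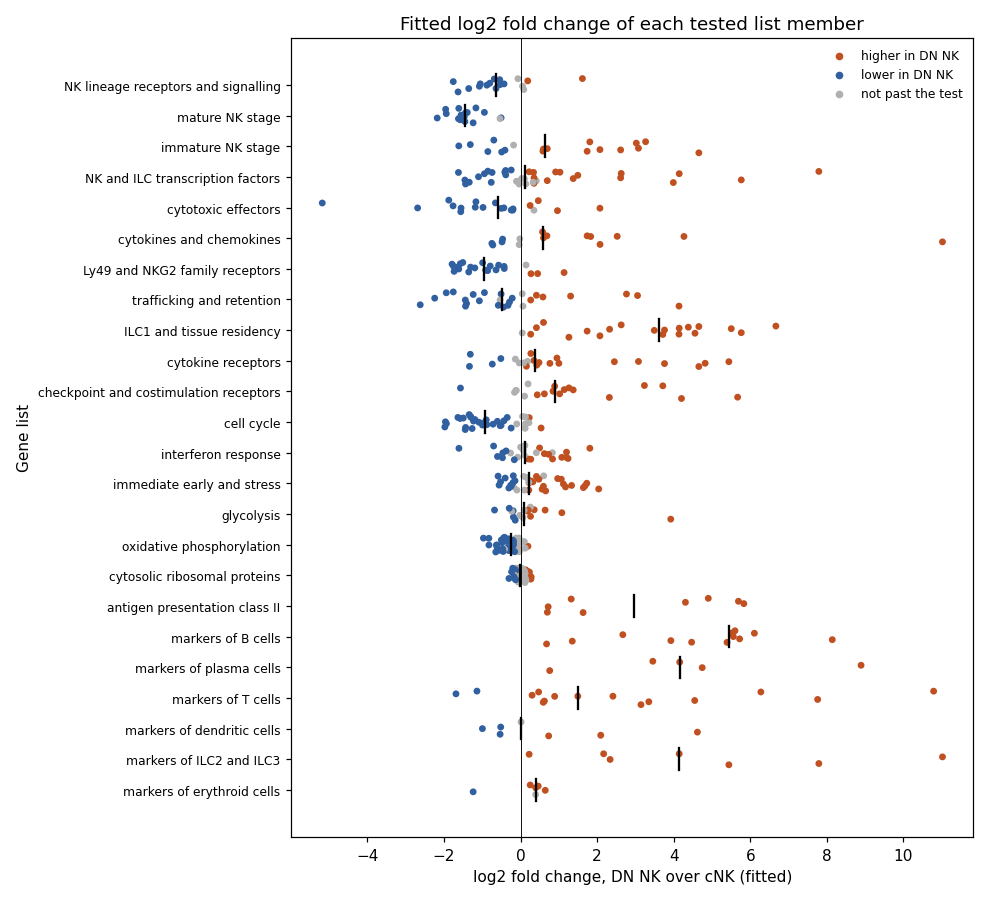
Fitted log2 fold change (DN NK over cNK) of each tested member of the 24 lists with at least 3 members, in orange where higher, blue where lower and grey where not past the test, with the list median as a black bar. The mature NK stage list lies left of 0 (median -1.46) and the ILC1 and tissue residency list right of it (median 3.60), and the points beyond 10 are genes with no reads in cNK, whose fitted size is no measured fold; the ribosomal protein calls depend on the scaling.

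Markers of other cell types differed between the groups. All 12 tested B cell markers were higher in DN NK, also adjusted over the list alone, with Pax5 at 2.31 ± 0.734 against 0.0450 ± 0.0151 FPKM. Blk had 2 read pairs in cNK and a ratio of 297 (95% counting interval 76.3 to 2290). The most abundant members were Ighm at 144 ± 22.7 against 93.9 ± 1.61 FPKM and Igkc at 95.7 ± 28.2 against 4.49 ± 1.67 FPKM. The excess over the cNK mean was larger in DN NK replicate 1 than in replicates 2 and 3, by a median factor of 1.51 over all 12, and each stayed higher without that library. The list had a camera adjusted p of 2.30e-10, and adjusted p = 0.125 with an estimated correlation. All 5 tested plasma cell markers rose, among them Irf4 (26.8-fold) and Iglv1 (17.8-fold), also adjusted over the list alone, and 7 of 8 rose without a filter. Igha, with 1 read pair in cNK, had a ratio of 522 with an interval of 99.2 to 22000. Their excess was 1.83 times as large in DN NK replicate 1 by the median, and camera gave adjusted p = 5.09e-05, and adjusted p = 0.168 with an estimated correlation. All 8 tested class II antigen presentation genes rose, also adjusted over the list alone, with H2-Aa at 89.0 ± 7.95 against 1.62 ± 0.272 FPKM, Cd74 at 166 ± 13.9 against 3.34 ± 0.684 FPKM and H2-Eb1 29.9-fold higher. The corresponding factor for DN NK replicate 1 was 1.11, and camera gave adjusted p = 2.79e-08, and adjusted p = 0.0574 with an estimated correlation.

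**Figure D3:**
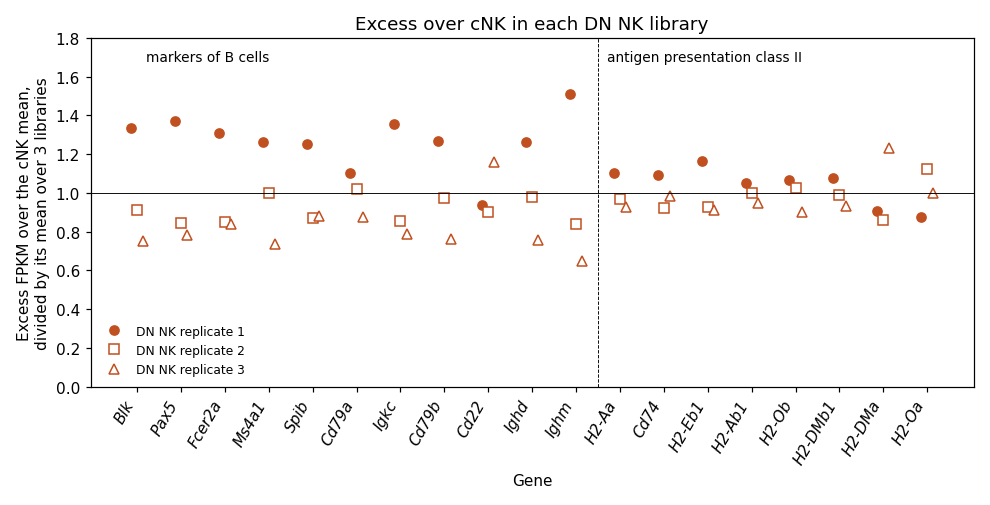
Excess FPKM over the cNK mean in each DN NK library for 11 of the 12 tested B cell markers and the 8 tested class II genes, divided by its mean over the 3 DN NK libraries (no unit; the filled circle is replicate 1, the square replicate 2 and the triangle replicate 3). Replicate 1 lies above the others for the B cell markers except Cd22, where its excess is 0.910 times that of the others, and less so for the class II genes, for which that ratio runs from 0.828 (H2-Oa) to 1.27 (H2-Eb1).

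T cell markers rose for 13 of 15 tested members and fell for 2, also adjusted over the list alone. Without a filter 17 of 22 rose and 2 fell. Tcrg-C2 was at 2.44 ± 0.232 FPKM against 0 in all cNK libraries, at least 61.8-fold higher. Cd4 was at 3.51 ± 0.290 against 0.0160 ± 0.0202 FPKM. Tcrg-C1 was 77.5-fold higher, at 8.99 ± 1.31 against 0.118 ± 0.114 FPKM. Cd3d rose by 3.14 and Cd3g by 2.41 on the log2 scale, while Trac, Trbc2 and Trbc1 rose by 0.59, 0.47 and 0.30. Trdc and Cd247 fell by 1.69 and 1.14. By camera the T cell list rose at adjusted p = 2.82e-05, and adjusted p = 0.0507 with an estimated correlation. All 7 tested ILC2 and ILC3 markers rose, also adjusted over the list alone, and 12 of 16 did so without a filter. Among them were Il22, Il1r1, Rora and Arg1. By camera this list rose at adjusted p = 1.05e-06, and adjusted p = 0.125 with an estimated correlation.

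The remaining lists of other cell types had few members high enough to test. Dendritic cell markers had 3 higher, 3 lower and 1 not past of 7, also adjusted over the list alone, with Batf3 24.6-fold and Zbtb46 4.27-fold higher and Naaa 2.00-fold lower, and camera adjusted p = 0.666. Erythroid genes had 4 of 6 higher and Hemgn lower, also adjusted over the list alone, with Hbb-bs and Hba-a1 at 1.56-fold and 1.38-fold higher and camera adjusted p = 0.651. The number higher was 2 without cNK replicate 3 and 1 without DN NK replicate 1. The haemoglobin calls were unstable: Hba-a1 was lost without cNK replicate 3 (adjusted p = 0.0716) and without DN NK replicate 1 (adjusted p = 0.0717; range over the alternatives 0.00508 to 0.0717), and Hbb-bs without DN NK replicate 1 (adjusted p = 0.0513; range 0.000956 to 0.0513). Of the monocyte and macrophage list only Cd68, which did not pass, and Ccr2, which fell, were high enough to test. Kit of the basophil and mast cell list and Pecam1 of the stroma and endothelium list rose, the latter 1.39-fold. Gp1bb of the platelet list was at a log2 fold change of -0.87 (SE 0.63, adjusted p = 0.276), and no neutrophil marker reached the filter. Without a filter, 3 of 8 neutrophil markers were higher and none lower, namely S100a9, Mmp9 and Lcn2, at up to 0.322 FPKM in DN NK. Of the basophil and mast cell list, 2 of 9 (Kit and Hdc) were then higher and none lower, and of the stroma and endothelium list 3 of 10 (Pecam1, Stab2 and Pdgfrb) and none lower. The same fit gave 5 higher and 3 lower of 14 dendritic cell markers, 1 higher and 2 lower of 20 monocyte and macrophage markers, 3 higher and 1 lower of 14 erythroid genes and 1 lower of 9 platelet markers.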

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

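The alternatives with DESeq2, the other edgeR scalings, edgeR's default filter and counts per read pair were chosen after seeing the data. In 24 alternatives, the 7215 genes past the threshold ranged from 4614 to 8912, and no gene called in both went the other way. Named genes kept their direction and their side of the threshold in 2066 of 2069 checks, and the other 3 were the haemoglobin losses given with the erythroid genes. Requiring a mean of 5 FPKM tested fewer rows (6801) and gave 4614 genes, 2278 higher and 2336 lower, with 592 changed at least 2-fold, 344 and 248. Dropping the filter gave 2824 at least 2-fold, 1852 higher and 972 lower, and edgeR's default filter 2794, 1819 and 975, since more low rows were tested. Limma on log2(FPKM + 1) gave 908 at least 2-fold (570 higher, 338 lower). With upper quartile scaling it gave 906 (567, 339), with quantile normalization 885 (543, 342), without a trend 904 (568, 336) and with array weights 909 (572, 337). The added pseudocount shrinks the folds of low genes. Camera with an estimated correlation called 2 lists in place of 18, and these runs differed only in the correlation used. Leaving out each library gave 6597 to 7044 genes and 1333 to 1593 at least 2-fold, and 17 to 18 lists. The share of calls that were higher was 49.9%, and it was 41.5% to 50.9% with the other edgeR scalings. With limma it was 44.3%, and 43.7% to 54.1% with its other scalings. Upper quartile scaling of the counts moved the median of all genes to -0.101, where the median of the mature NK stage list was -1.55. Of list calls by camera, 18 of 550 checks were lost (9 cytokines, 4 immature stage, 4 immediate early, 1 trafficking) and 2 gained (ribosomal proteins, in opposite directions); the cause was not tested. Counts of list members higher or lower moved by over 1.5 times in 91 of 1342 checks. With a mean of 5 FPKM fewer members were tested, and those higher numbered 9 transcription factors, 7 immature stage, 7 interferon, 2 cytotoxic, 8 T cell, 4 B cell, 2 plasma cell, 2 ILC2 or ILC3 and 1 dendritic cell genes. Limma on rescaled values gave 3 glycolysis genes lower and 2 oxidative phosphorylation genes higher, and edgeR's default filter 14 ILC2 or ILC3 markers higher. With a replicate block 7222 genes passed. Libraries with the same number deviated together with correlations of 0.046, 0.036 and 0.162, against -0.098 to 0.056 between groups for other numbers. Replicate 1 of cNK correlated best with DN NK replicate 2 (0.056), while cNK replicates 2 and 3 correlated best with their own number. These values do not decide whether the numbers mark pairs. The labels state no pairing, so the block stayed an alternative. In simulation 7 of the 50 genes with the smallest change were recovered against 62% at 1.5-fold, so small differences can be missed at this depth and number of libraries.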

Other observations

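The KEGG tests, the splits and the tests of explanations in this part were chosen after the results were seen, while the fit without a filter and the limma scalings that some of them use were planned. The KEGG pathways of the deposited annotation gave a wider view of the differences. Of 280 pathways with 10 to 300 tested genes, camera called 31 with its preset correlation, 21 up and 10 down in DN NK. With an estimated correlation it called none of the 280. An unadjusted p under 0.05 was reached by 17, about as many as chance would give, so the pathways below are given by their genes. Over all 11690 tested rows, 3602 were higher and 3613 lower. The pathways given here are a selection from the 31, with no rule fixed beforehand. Hematopoietic cell lineage, with the lowest camera p, had 27 of 43 genes higher and 9 lower. Antigen processing and presentation had 35 of 59 higher and 8 lower. Both had adjusted p = 0.549 by camera with an estimated correlation. Th17 cell differentiation had 48 of 81 genes higher and 17 lower (adjusted p = 2.26e-05, and adjusted p = 0.549 with an estimated correlation). The NF-kappa B pathway had 39 of 70 higher and 14 lower (adjusted p = 0.00581), the spliceosome 65 of 119 and 22, ribosome biogenesis 36 of 70 and 13, and Notch signalling 24 of 38 and 5, each at adjusted p = 0.623 with an estimated correlation. The citrate cycle had 20 of 27 genes lower and 2 higher, DNA replication 20 of 33 lower and 2 higher, and natural killer cell mediated cytotoxicity 47 of 97 lower and 27 higher (adjusted p = 0.0207). These 3 also had adjusted p = 0.623 with an estimated correlation.

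With 3 libraries against 3, only 10 splits exist, too few for a share under 0.05. The real split called 7215 genes and the highest other split 2, so 1 of the 10 splits reached the real count. For changes of at least 2-fold the real split gave 1472 and the highest other 2, again 1 of 10. Every other split mixes libraries of the 2 groups, so the difference between the groups raises the spread within each side. The low counts of these splits follow from that and do not measure what chance would give.

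B cell markers were higher in DN NK for all 12 tested members. Reads shared between immunoglobulin segments are argued against as the whole cause, since the 9 tested members that are not immunoglobulin genes had a median log2 fold change of 5.56, all past the threshold. B cells or their RNA in the DN NK libraries and expression by DN NK cells cannot be told apart: the 5 members below the filter were higher too (median 3.34 in the fit without a filter), but only 4 of the 17 members reach 1 FPKM in cNK, so the filter divides the list by the rise itself, and both sources would give that value. Nor can it be told whether any B cells also brought the class II rise: the excess in DN NK replicate 1 was 1.114 times that of replicates 2 and 3 for class II genes (median) and 1.51 times for B cell genes, from 0.910 (Cd22) to 2.03 (Ighm), and a single library decides this. The median ratio was 0.927 for T cell markers and 0.959 for ILC1 and residency genes that rose. Any gate against B cells is not given in the sources used here.

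Of 15 tested T cell markers 13 rose and 2 fell (Trdc and Cd247), and all 7 tested ILC2 or ILC3 markers rose. T cells as the source of Cd3d and Cd3g are argued against, since the excess of Cd3e over cNK was only 0.0344 times the mean excess of Cd3d and Cd3g (0.824 against 24.0 FPKM), although every mature T cell carries all 3 chains. A small share of T cells remains open, as Cd3e itself was higher. ILC2 or ILC3 cells in the fraction and NK cells expressing their genes cannot be told apart: 66.7% of the 9 list members below the filter were higher too, but only 2 of the 16 members reach 1 FPKM in cNK, so the filter divides this list by the rise itself and the value favours neither. In addition, 10 of the 16 members also stand in another list.

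Of 71 distinct tested members of the 4 lists of NK receptor, mature-stage and cytotoxic genes, 56 fell in DN NK, 9 rose and 6 did not pass. A lower share of NK cells beside cells without these genes is argued against as the whole cause, because it would lower them by 1 common factor, and the log2 fold changes of the 56 alone had an SD of 0.773 against a median standard error of 0.063 (1.036 over all 71). Cells that express some of these genes would not give 1 common factor, so the SD does not bear on dilution by such cells. The choice among 6 scalings changed little, since the median of the mature NK stage list stayed at -1.381 or lower under each. These scalings kept the median of all tested genes between -0.101 and 0.017. They were too alike to remove the shift of the list, so a scaling error common to them is not tested. A lower content per cell, or fewer mature cells among the NK cells of the DN NK group, stays open as an untested biological reading of the design. So does a dilution by other cells that is partial or comes from cells with some of these genes.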
